A study of Mus musculus with 6 samples.

How the data were processed

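Total RNA of whole testes from 4-day-old mice of the FVB strain was measured on Illumina bead arrays, 3 arrays labelled Foxo1 null and 3 labelled wild type, all on 1 slide. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase I, checked on a Bioanalyzer, and amplified to biotinylated cRNA with the Ambion MessageAmp kit. The submitters' processing notes name BeadStudio, Illumina's array software, with no version or settings.

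Per the file headers, the deposited scanner table holds for each of 45281 probes on each array a mean bead intensity, the standard error of that intensity over beads, the number of beads, and a detection p-value, the share of negative control signals at or above the probe's own. These intensities were neither normalized between arrays nor background-subtracted: their medians differed between arrays and no value was below 0. A second deposited table, also of intensity, holds the authors' normalized values; each of its columns ranked the probes as the same sample's scanner signal did (Spearman correlation 1 for all 6 arrays), on a linear scale, with column medians from 130.61 to 130.71 and no background subtraction. Its scale and direction are thus those of the scanner signal, and it served as an alternative only. No table held a column that was left unmapped to a sample.

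The analysis started from the scanner intensities. Background was corrected with limma 3.58.1 in R 4.3.3 by its neqc function, which fits a normal-plus-exponential model with the background inferred from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Because of the offset and the background model, log2 changes of dim probes depend on these settings. A probe was tested if its detection p-value was under 0.05 on at least 3 of the 6 arrays, which left 20597 probes. Differences, always null minus wild type, were fitted per probe with limma's lmFit and eBayes without covariates. P-values were two-sided and adjusted over all tested probes by the Benjamini-Hochberg method with a threshold of 0.05. A probe undetected on every array of a group has only a bound there: its fold is given as "at least", from the brighter group's mean against the mean of, per array, the higher of the lowest normalized value among detected probes and the probe's own value.

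Probes were named from the platform's annotation table, and symbols were updated through Entrez gene numbers to a gene table of assembly GRCm38.p6. On the whole array 34885 probes had 1 gene symbol, 18 had several and 10378 had none; of the tested probes, 17503, 9 and 3085. Probes with several symbols were left unnamed. Of the annotated probes, 34807 had an Entrez number in the gene table and 0 changed their symbol. No genomic coordinates are given, because neither the labels nor the tables name a genome build. Of 4322 genes with 2 or more tested probes, 8 had probes on opposite sides of 0 at an unadjusted p-value under 0.05.

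A total of 27 gene lists were written down from background knowledge: germ cell states, somatic cell types of the testis, cell types and tissues that a dissection could carry along, and pathways. They hold 654 distinct genes, of which 447 were tested; 70 list symbols had no named probe. Each gene entered by 1 probe, the tested one with the highest mean. List shifts were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list's members with all other tested genes (11145 genes in all), and adjusted over the 27 lists. Camera with the correlation estimated per list, and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, were alternatives. An array's list score is the mean log2 value of the tested members relative to their wild-type mean. Scores of single lists were compared by exact permutation tests, two-sided, whose smallest possible p with 3 against 3 arrays is 0.1.

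The comparison, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names 4 FoxO genes and 12 germ cell genes (Ret, Kit, Gfra1, Zbtb16, Sall4, Etv5, Bcl6b, Lhx1, Egr4, Stra8, Ddx4 and Dppa4), up to 12 genes per direction with the largest change among probes past the threshold whose groups do not overlap (1 probe per gene, the one with the highest mean), and in each list up to 4 tested members with the smallest unadjusted p-value. The alternatives were no background correction, another normexp fit with an offset of 50, median scaling, cyclic loess, the authors' normalized values, no filter or a filter on detection on all 6 arrays, a trended and robust variance prior, array weights, the replicate number as a block, slide position as a covariate, a fold minimum of 1.5, an adjusted p-value under 0.1, all probes of a gene averaged, and leaving out each array in turn. Added after seeing the data were a duct epithelium score as a covariate, and the lists without Foxo1.

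The fit was tested on simulated data built on the real probes of this comparison (20597 probes, 3 against 3 arrays). It called 73.75% of 80 planted changes of 1 log2 unit, and 100% of those of 2 and of 3 units, with 11 false calls among 190. A shift of 0.5 planted in the macrophage list was called and 0 other lists were. The simulated genes varied independently of one another, so this cannot test the preset correlation. In the real data the estimated correlation was 0.21 for the macrophage list and 0.63 for the pan germ cell list. It was lower for undifferentiated spermatogonia (0.079), GDNF-responsive genes (0.058) and cholesterol synthesis (-0.048). The number of arrays limits the precision: the median residual SD of a tested probe was 0.23 log2 units, against a median standard error between beads of 0.07. No label says that the arrays come from separate animals, so the p-values measure the spread between these samples, part of which may be technical. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.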

Results

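Gene expression was measured in testes of mice at postnatal day 4, when the seminiferous cords hold Sertoli cells and young spermatogonia, in 3 samples labelled Foxo1 null and 3 labelled wild type. Foxo1 encodes a forkhead transcription factor that is held in the cytoplasm by PI3K-AKT signalling. The arrays detected between 20107 and 21665 of 45281 probes (44.4% to 47.8%), with a median of 43 beads per probe on every array. The single comparison, null against wild type, asks which transcripts of the young testis depend on Foxo1, in a study of spermatogonial stem cells and the start of spermatogenesis.

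Foxo1 itself was measured by 2 probes that changed in opposite directions. At probe ILMN_2656498 the normalized log2 intensity was 8.11 ± 0.06 (SD, n = 3) in wild type and 6.30 ± 0.43 (SD, n = 3) in null arrays, a change of -1.81 (SE 0.22) or 3.52-fold, with an adjusted p = 0.0273 (limma, Benjamini-Hochberg). At probe ILMN_2509340 it was 5.36 ± 0.37 (SD, n = 3) in wild type and 8.72 ± 0.13 (SD, n = 3) in null arrays, a change of 3.36 (SE 0.20) or 10.2-fold higher, with an adjusted p = 0.00221 (limma, Benjamini-Hochberg), the smallest of all probes. The unnormalized signals of this probe were 133 to 136 in wild type, where it was detected on 2 of 3 arrays, and 467 to 621 in null. All 6 arrays lay on their own group's side at both probes. A probe outside a deleted part of the gene checks nothing about the genotype, and the places of the 2 probes within Foxo1 were not analysed here. The sizes depend on the background correction: without it the changes were -1.0 and 1.78. The call at ILMN_2656498 was lost with median scaling (adjusted p = 0.0513, limma), with no filter on dim probes (adjusted p = 0.0669, limma), and without any 1 array other than null replicate 1 (adjusted p from 0.102 to 0.125, limma).

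Among the other FoxO genes, the only tested Foxo3 probe changed by -1.16 (SE 0.24, n = 3 per group), from 6.89 to 5.73, which passed no adjustment over all probes (adjusted p = 0.152, limma with Benjamini-Hochberg). The 2 tested Foxo6 probes had values of -0.07 (SE 0.29) and 0.02 (SE 0.27), and Foxo4 was detected on 1 array and not tested.

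Across all genes the called changes lay almost wholly on the lower side in the null testes. Nanos2, an RNA-binding protein that maintains male germline stem cells, fell 3.75-fold (-1.91, SE 0.20), and Egr2, a zinc finger transcription factor induced by growth factor signalling, 3.75-fold (-1.91, SE 0.22). Ret, the receptor tyrosine kinase for GDNF, fell at the called probe (-1.75, SE 0.20), as did Dppa4, a nuclear protein of pluripotent and early germ cells (-1.54, SE 0.17). The largest change of a called lower gene was that of Fgl1, a secreted fibrinogen-like protein, 7.5-fold at its brighter probe (-2.91, SE 0.26) and 4.55-fold at the other. Nudt6, which encodes a Nudix hydrolase, fell 4.34-fold (-2.12, SE 0.15) and had the smallest p among the lower probes. Each of these values rests on n = 3 per group, with all 3 null arrays below all 3 wild-type arrays, and the adjusted p of these genes lay between 0.0043 and 0.0239 (limma, Benjamini-Hochberg). The called Ret and Dppa4 probes were detected on 1 of 3 null arrays and Nanos2 on 2, so their sizes are set against values near background: without background correction they were -0.62, -0.51 and -0.74, and the Dppa4 call was lost (adjusted p = 0.0631, limma).

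In all, 28 of 20597 tested probes passed the threshold, 26 lower and 2 higher in null; the lower ones belong to 22 named genes and 2 unnamed probes. The remaining genes of the naming rule fell as well: Crygs, a lens crystallin (-2.08), Ssxb8, a member of the SSX family (-1.98), Actn2, an actin cross-linker (-1.71), Cd274, the immune checkpoint ligand PD-L1 (-1.64), Cela2a, an elastase (-1.60), and Sdcbp2, a syntenin (-1.57). Crygs, Ssxb8 and Cd274 were detected on 1 of 3 null arrays. Named after their values were seen, the others were Ovol2 (-1.23 at the brighter of 2 called probes), Foxr1 (-1.52), Spint5 (-1.45), Rapsn (-1.43), Esrp1 (-1.37) and Stx3 (-1.22). Zfp985, Dlx3 and Elmo1 were undetected on all null arrays and were at least 2.17-fold, 2.07-fold and 1.81-fold lower. The only called higher gene other than Foxo1 was Moxd1, a monooxygenase related to dopamine beta-hydroxylase, at 4.35-fold (2.12, SE 0.21, adjusted p = 0.0239, limma).

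At an unadjusted p under 0.05 there were 979 lower and 831 higher probes, 1810 against 1030 by chance, and the groups did not overlap at 13.96% of the tested probes, where chance gives 10%. The counts of 26 and 2 rest on all 6 arrays: they were 46 and 24 without null replicate 1, and 0 and 1 without null replicate 2 (limma; 760 lower and 695 higher at an unadjusted p under 0.05). Leaving out null replicate 3 gave 1 and 1, and leaving out wild-type replicates 1, 2 and 3 gave 1, 4 and 3 lower with 1, 2 and 1 higher. They also moved with the variance model and the filter, from 1 lower probe without a filter on dim probes to 85 with a trended, robust prior.

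**Figure D1:**
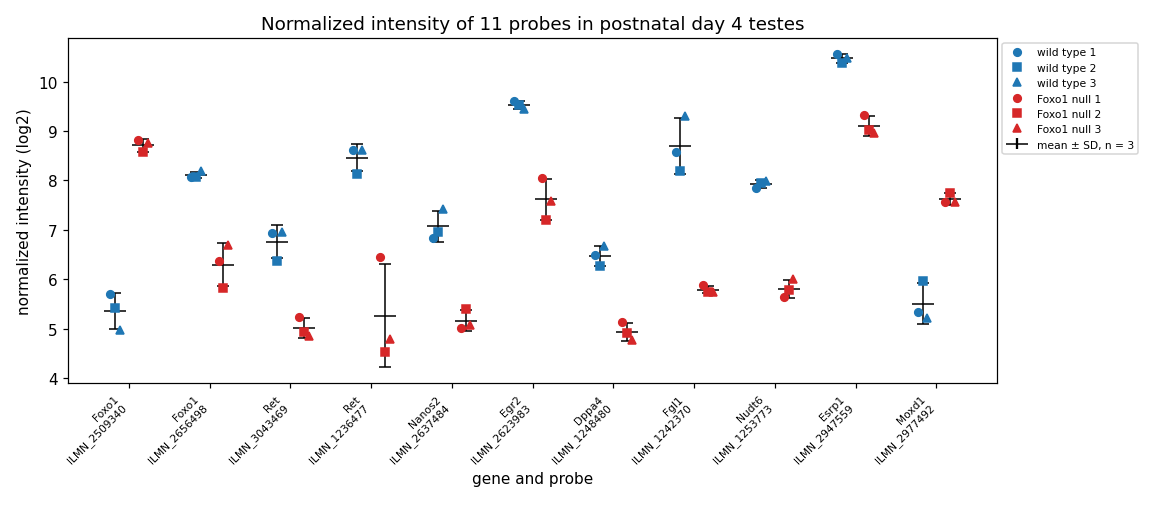
Normalized intensity (log2, vertical axis) of 11 probes (horizontal axis, gene and probe) on the 3 wild-type arrays (blue) and the 3 Foxo1 null arrays (red); symbols mark replicates, and black bars the mean ± SD of n = 3. The groups do not overlap at any of these probes; at the brighter Ret probe, ILMN_1236477, the null arrays spread widely, and its adjusted p was 0.052 (limma, Benjamini-Hochberg).

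Of the 12 germ cell genes fixed beforehand, only Ret and Dppa4 had a called probe. At the brighter probes of these genes and in several others the values were larger and the spread wider. The brighter Ret probe had a change of -3.20 (SE 0.45, adjusted p = 0.052), the brighter Dppa4 probe -2.27 (SE 0.34, adjusted p = 0.0714), Egr4 -2.46 (SE 0.54, adjusted p = 0.188), Sall4 -2.35 (SE 0.51, adjusted p = 0.185) and Lhx1 -1.78 (SE 0.34, adjusted p = 0.127), all limma with Benjamini-Hochberg adjustment over all probes. At each of these probes the 3 null arrays lay below the 3 wild-type arrays; the brighter Ret probe was detected on 1 of the null arrays. A further tested Dppa4 probe, ILMN_3155408, was at -0.61 (SE 0.34, adjusted p = 0.686) with overlapping groups, null replicate 1 lying above all wild-type arrays. Values nearer 0 were those of Bcl6b (-0.91, SE 0.33), Ddx4 (-0.78, SE 0.22), Etv5 (-0.43, SE 0.16) and Zbtb16 (-0.29, SE 0.26). Kit, the receptor of differentiating spermatogonia, and Stra8, which responds to retinoic acid at the entry to meiosis, had positive values of 0.20 (SE 0.20) and 0.76 (SE 0.58) that did not pass the test. The dimmer of the 2 tested Kit probes, detected on 1 of 3 wild-type arrays, was at 0.45 (SE 0.21), and the second tested probes of Sall4, Lhx1 and Etv5 at -1.87 (SE 0.41), -1.70 (SE 0.38) and -0.52 (SE 0.23), also without passing. Gfra1, the GDNF co-receptor, was detected on no array and was not tested.

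The list of genes of undifferentiated spermatogonia passed as lower by limma's camera with the preset correlation (adjusted p = 2.67e-14), but not with an estimated correlation (adjusted p = 0.152). Of 29 tested members, 2 (Nanos2 and Foxo1 itself) were lower over all genes tested. Foxo1 entered by the probe with the higher mean, ILMN_2656498, while its other probe rose by 3.36. Adjusted over the list alone, 16 members fell, 1 rose and 12 did not pass. The median change was -0.91 and the mean score -0.99, in a range from -0.73 to -1.18 on the null arrays against -0.16 to 0.17 on the wild-type arrays. Past the threshold over the list alone were also Tcl1, an AKT coactivator (-3.17, SE 0.45), and the brighter Ret probe. The member that rose, named after its value was seen, was Thy1, a surface glycoprotein also found on stromal cells and T cells (1.08, SE 0.33). The list median was -0.38 without background correction, -0.41 with the authors' normalized values and -0.51 without wild-type replicate 3, past the threshold by camera in each.

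Of the 15 tested genes that respond to GDNF, the growth factor of spermatogonial stem cells, 2 (Nanos2 and Egr2) were lower over all genes tested and 5 fell adjusted over the list alone. Next to these 2, they included Lhx1, a LIM homeobox factor (-1.78), Egr3, a relative of Egr2 (-0.86, SE 0.17), and, named after its value was seen, Id4, an inhibitor of basic helix-loop-helix factors (-1.33, SE 0.29). The median change was -0.44, with an adjusted p = 1.08e-07 by camera and an adjusted p = 0.152 with an estimated correlation. Without null replicate 1 the median was -0.95. This list shares 8 tested genes with that of undifferentiated spermatogonia, so the lists are not independent.

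Of markers common to germ cells of several stages, the pan germ cell list passed as lower by camera (adjusted p = 1.66e-19), but not with an estimated correlation (adjusted p = 0.279) or by fry (adjusted p = 0.154). All 26 tested members had negative values, with a median of -1.0; 0 passed over all genes tested and 19 fell adjusted over the list alone. The members with the smallest p were Dppa4, the RNA-binding proteins Dnd1 (-1.04, SE 0.16) and Nanos3 (at least 2.32-fold lower, undetected on the null arrays), and Stk31, a germ cell kinase (-1.39, SE 0.24). In the piRNA pathway, which silences transposons in the germline, 13 of 16 tested members fell adjusted over the list alone and 0 over all genes tested, with a median of -0.96. Examples are Piwil1 (-0.94, SE 0.18), Gtsf1 (-1.50, SE 0.30), Tdrd12 (-1.0, SE 0.22) and Tex19.1 (-1.36, SE 0.36). Its adjusted p was 7.40e-13 by camera, 0.279 with an estimated correlation and 0.154 by fry; 11 of its tested genes are also in the pan germ cell list. Without background correction the median of either list was -0.56. Among the wild-type arrays, replicate 3 stood above the others in both lists, with pan germ cell scores of 0.46 against -0.19 and -0.27.

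Of 12 tested markers of differentiating spermatogonia 0 passed, over all genes tested or adjusted over the list alone, and 3 had an unadjusted p under 0.05: Ccnd1, a G1 cyclin (0.73, SE 0.23), Kdm1b, a histone demethylase (-0.53, SE 0.20), and Uhrf1, a factor of maintenance methylation (-0.50, SE 0.20). The median change was 0.19 and the camera adjusted p = 0.959. Single arrays moved this median, which was 0.03 without wild-type replicate 2, 0.096 without wild-type replicate 1, 0.12 without null replicate 3 and 0.24 without wild-type replicate 3 (adjusted p = 0.0591, the smallest of these 4). Of 15 tested meiotic genes 0 passed either adjustment (median -0.16, adjusted p = 0.308 by camera), the smallest p being that of Syce3, a synaptonemal complex protein (-0.79, SE 0.21). Single arrays decided this: by camera with the preset correlation, the meiotic list passed as lower without null replicate 3 (median -0.46, adjusted p = 0.00209) and without wild-type replicate 1 (-0.30, adjusted p = 0.042). Its median was 0.08 without wild-type replicate 3 and 0.01 without null replicate 2. With an estimated correlation the adjusted p of the meiotic list was 0.93 by camera on all arrays. Of 14 tested X-linked spermatogonial genes 0 passed over all genes tested; adjusted over the list alone Mageb4 (-1.26, SE 0.31) and Rhox10 (-1.78, SE 0.48) fell and Magea5 (0.75, SE 0.21) rose, with a list median of -0.18 (adjusted p = 0.105 by camera). By camera with the preset correlation, the X-linked list too passed as lower in 5 of 20 planned settings. Among them were leaving out null replicate 3 (-0.45, adjusted p = 0.00124), wild-type replicate 1 (-0.29, adjusted p = 0.0171) or wild-type replicate 2 (-0.35, adjusted p = 0.0174), and median scaling (adjusted p = 0.0174). Its median was 0.01 without wild-type replicate 3. With an estimated correlation its adjusted p was 0.83 by camera on all arrays.

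**Figure D2:**
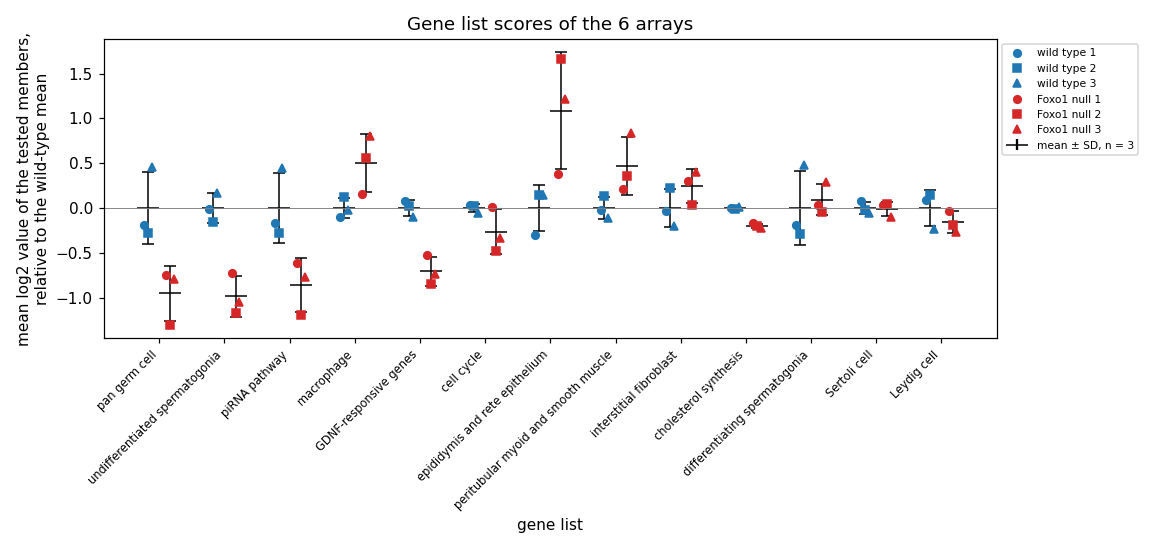
Mean log2 value of the tested members of 13 gene lists on each array, relative to the wild-type mean (vertical axis), for the 10 lists past the threshold and the differentiating, Sertoli and Leydig lists (horizontal axis); colours mark genotype, symbols replicates, and bars the mean ± SD of n = 3. The germ cell lists past the threshold lie lower on all 3 null arrays, from -0.75 to -1.30 for the pan germ cell list. The differentiating list does not, at -0.05 to 0.29 on the null arrays and -0.29 to 0.48 on the wild-type arrays. The epididymis and rete list is highest on null replicates 2 and 3, at 1.66 and 1.21.

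Sertoli cells, the somatic cells of the cords, showed no shift: 0 of 27 tested markers passed either adjustment, the median was 0.01, the mean -0.01 and the camera direction down, with an adjusted p = 0.959. The smallest p was that of Rhox5, a homeobox factor (-0.87, SE 0.21). Leydig cell genes, which make androgens, had a median of -0.15 with 0 of 17 tested members past either adjustment (adjusted p = 0.167 by camera); Star, which carries cholesterol into mitochondria, was at -0.81 (SE 0.29). By camera with the preset correlation, the Leydig list passed as lower without wild-type replicate 3 (-0.30, adjusted p = 0.00703), with array weights (-0.21, adjusted p = 0.024) and with slide position as a covariate (-0.18, adjusted p = 0.0313). With an estimated correlation the adjusted p of the Leydig list was 0.81 by camera on all arrays. The median of this list was nearer 0 without wild-type replicate 2 (-0.014, adjusted p = 0.662) and without null replicate 3 (-0.047, adjusted p = 0.489), both with the preset correlation.

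Of the lists of other cell types, 4 passed as higher by camera with the preset correlation and 0 with an estimated correlation (adjusted p from 0.279 to 0.561). In the macrophage list 0 of 19 tested members passed over all genes tested and 7 rose adjusted over the list alone, among them C1qc, a complement component (0.86, SE 0.19), Mrc1, the mannose receptor (0.64, SE 0.15), Laptm5 (0.56, SE 0.16) and C1qa (0.54, SE 0.16); the median was 0.55, and 0.28 without background correction. Its adjusted p was 2.12e-08 by camera, 0.279 with an estimated correlation and 0.154 by fry. In the epididymis and rete epithelium list 6 of 9 tested members rose adjusted over the list alone and 0 over all genes tested, with a median of 0.72. They included Cdh16, a cadherin (2.47, SE 0.61), Krt19, a keratin (1.49, SE 0.43), Lcn2, a lipocalin (2.40, SE 0.75), and Krt8 (0.69, SE 0.24). Its adjusted p was 1.49e-05 by camera, 0.279 with an estimated correlation and 0.179 by fry. Macrophage scores on null replicates 1, 2 and 3 were 0.15, 0.55 and 0.80. The scores of the epididymis and rete list on the same arrays were 0.38, 1.66 and 1.21, and those of wild type lay between -0.30 and 0.15. They were highest on the null arrays on which the undifferentiated list was lowest, at -1.18 and -1.05. The epididymis and rete score correlates with genotype (0.802), so a fit of both on 6 arrays separates them poorly. With this score as a covariate, added after seeing the data, limma called 0 probes (620 lower and 562 higher at an unadjusted p under 0.05). By camera with the preset correlation, 6 of the 10 lists kept their call. Of these, the medians were -0.75 for the undifferentiated list (adjusted p = 3.01e-07), -0.70 for pan germ cell (adjusted p = 6.56e-08), -0.59 for piRNA (adjusted p = 0.000378), -0.13 for GDNF-responsive genes, from -0.44 (adjusted p = 0.0093), 0.39 for interstitial fibroblast (adjusted p = 0.00155) and 0.34 for peritubular genes (adjusted p = 0.0482). The 4 lists that lost it were macrophage (median 0.17, adjusted p = 0.249), cell cycle (0.13, adjusted p = 0.249), cholesterol synthesis (-0.21, adjusted p = 0.0743) and the epididymis and rete list (-0.065, adjusted p = 0.831), whose loss says nothing because the covariate is its own score. Outside the 10, the mast cell list then passed as higher (1.40, adjusted p = 0.00329), and the adipocyte (-0.56, adjusted p = 0.0208), erythroid (-0.29, adjusted p = 0.043) and interferon lists (-0.18, adjusted p = 0.0482) as lower.

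Peritubular myoid and smooth muscle genes had a median of 0.46, with 14 of 15 tested members above 0 and 0 past either adjustment. Actg2, a smooth muscle actin (1.42, SE 0.40), and Tpm2, a tropomyosin (0.62, SE 0.20), had the smallest p. The list's adjusted p was 2.02e-05 by camera and 0.431 with an estimated correlation. Interstitial fibroblast genes had a median of 0.24, with 0 of 19 tested members past either adjustment; Lum, a matrix proteoglycan, was at 0.87 (SE 0.29). Their adjusted p was 0.00234 by camera and 0.561 with an estimated correlation, and without wild-type replicate 3 the median was 0.14 (adjusted p = 0.0918 by camera). Null replicate 2 scored 0.03, within the wild-type range of -0.20 to 0.23. Among mast cell and lymphocyte genes, the mast cell proteases Cpa3 (1.33, SE 0.35) and Cma1 (1.17, SE 0.34) rose adjusted over the list alone, 2 of 6 tested members, with a list median of 0.23 (adjusted p = 0.0802 by camera). The list passed as higher without null replicate 2 (0.55, adjusted p = 0.0477), without null replicate 3 (0.28, adjusted p = 0.0271) and with no filter on dim probes (0.21, adjusted p = 0.0144), but its median was 0.047 without null replicate 1 (adjusted p = 0.444), which scored 0.95 against 0.16 and 0.34 on the other null arrays. Endothelial genes had a median of 0.08 with 0 of 16 tested members past either adjustment (adjusted p = 0.0537 by camera). They passed as higher in 10 of 20 planned settings, with adjusted p down to 0.0191 without null replicate 2, and not in the others, such as with an estimated correlation (adjusted p = 0.342). With 1 array left out the median ranged from 0.04 without wild-type replicate 2 (adjusted p = 0.189) to 0.18 without wild-type replicate 3 (adjusted p = 0.0762); it was 0.16 without wild-type replicate 1, null replicate 1 or null replicate 2, and 0.05 without null replicate 3.

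Cell cycle genes had a median of -0.26: 26 of 30 tested members were below 0 and 0 passed either adjustment, with the DNA replication factors Mcm3 (-0.69, SE 0.18) and Cdc45 (-0.51, SE 0.17) at the smallest p. The adjusted p was 6.57e-07 by camera and 0.436 with an estimated correlation. Their score on null replicate 1 was 0.01, within the wild-type range of -0.06 to 0.03, and -0.48 and -0.33 on the other null arrays; the list median was -0.41 without null replicate 1 and -0.17 without null replicate 2. Cholesterol synthesis genes had a median of -0.25, and 1 of 15 tested members, Lss, lanosterol synthase (-0.80, SE 0.15), fell adjusted over the list alone, 0 over all genes tested. All 3 null arrays scored between -0.17 and -0.22 against -0.01 to 0.01 in wild type (exact permutation p = 0.1, n = 3 per group, the smallest that 3 against 3 allow). The list's adjusted p was 0.00234 by camera and 0.213 with an estimated correlation, and its median was -0.15 without wild-type replicate 3 or null replicate 3.

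FoxO target genes as a list did not shift, with a median of 0.03 over 30 tested members and an adjusted p = 0.507 by camera; only Foxo3 fell adjusted over the list alone. In the PI3K-AKT list 2 of 23 tested members fell adjusted over the list alone, Foxo3 and Pik3cd, a catalytic subunit of PI3K (-0.94, SE 0.19), with a median of -0.05 (adjusted p = 0.229 by camera). Neither list had a member past the threshold over all genes tested.

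The other lists had 0 members past either adjustment and camera adjusted p from 0.67 to 0.987. Their medians were 0.01 for p53 and apoptosis, -0.03 for the interferon response, 0.11 for adipocyte genes, 0.04 for oxidative phosphorylation, 0.02 for ribosomal proteins, 0.01 for immediate early and heat shock genes and -0.03 for erythroid genes. Single arrays moved some of these without a call. The adipocyte median was -0.23 without null replicate 2 and 0.29 without wild-type replicate 3. The interferon median was -0.13 without null replicate 2, and the immediate early median 0.20 without null replicate 1. Skeletal muscle genes had a median of -0.14 and a mean of 0.07, of opposite sign, with the test's direction down. In all, 10 of 27 lists passed with the preset correlation, 6 lower and 4 higher. With an estimated correlation 0 passed (4 at an unadjusted p under 0.05), and 3 passed by fry: undifferentiated spermatogonia and GDNF-responsive genes (adjusted p = 0.0156 for both) and cholesterol synthesis (adjusted p = 0.00496).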

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

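The duct epithelium score as a covariate, and the lists without Foxo1, were chosen after seeing the data; the other settings were planned. Leaving aside Foxo1, whose probes are given below, the 13 named probes past the threshold kept their direction in all 240 comparisons with other settings and fell short of the threshold in 92. The kept direction says little: their groups do not overlap, so leaving out 1 array cannot change it. The filters and the variance prior leave the log2 changes as they are. Of the 10 lists past it, 198 of 220 comparisons kept direction and call, 20 lost the call and 2 reversed, one of them the epididymis list against its own score. The list count of 10 was 10 to 13 elsewhere, but 0 by camera with an estimated correlation (4 at an unadjusted p under 0.05) and 3 by fry. The 2 forms of camera differ in more than the correlation. For the PI3K-AKT list the estimate was 0.0099, close to the preset 0.01, yet the unadjusted camera p was 0.201 against 0.127. For cholesterol synthesis the estimate was -0.048, below the preset, yet the unadjusted camera p was 0.0236 against 0.000865. The lost call of that list is thus not due to a higher correlation, and the correlation alone does not carry all 10 calls. Fry asks another question, without comparing a list with other genes. The 17 other lists passed with the same sign in 26 of 372 comparisons, and in 1 the adipocyte list passed with its sign reversed.

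The 26 lower and 2 higher probes became 45 and 8 without background correction, 70 and 11 with the other normexp fit, 45 and 8 with the authors' normalized values, 85 and 18 with a trended, robust prior, 83 and 26 with array weights and 66 and 10 at an adjusted p under 0.1. They were 1 and 1 without a filter, where 45281 probes were adjusted together, and 17 and 1 for probes detected on all 6 arrays, which leaves the higher Foxo1 probe untested. Median scaling gave 12 lower probes and moved the median of all tested probes to 0.12, against which its changes are to be read; slide position as a covariate gave 6 higher. With 5 arrays, lower probes ranged from 0 (without null replicate 2) to 46 (without null replicate 1) and higher probes from 1 to 24. The cause of these changes, the smaller number of arrays included, was not tested.

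With the replicate number as a block, 51 probes were lower and 17 higher, 26 of them shared with the 28. Correlations of the deviations of arrays with the same number were 0.158, -0.0957 and 0.106 for numbers 1, 2 and 3. Those of arrays with different numbers ran from -0.179 to 0.09, below the values for numbers 1 and 3 but not for number 2. This leaves a pairing undecided, and the numbers are not taken to pair the arrays because no label says so.

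The lower Foxo1 probe was at -1.69 with median scaling (the cause of the lost call was not tested), at -1.81 without a filter and, over arrays left out in turn, at -2.01 to -1.58, past the threshold there only without null replicate 1; averaging all Foxo1 probes gave 0.77, since opposite changes were averaged. With the duct score as a covariate, which correlates with genotype (0.802), limma called 0 lower and 0 higher probes (620 and 562 at an unadjusted p under 0.05). The Foxo1 probes were then at -1.53 (adjusted p = 0.846) and 3.69 (adjusted p = 0.128), and the medians of the adipocyte, cell cycle and epididymis lists at -0.56, 0.13 and -0.065. Dim signals limit the folds: the higher Foxo1 probe was at 1.78 without background correction, against 3.36 with it. Over all settings it ranged from 1.78 to 3.69, the upper end being the fit with the duct score.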

Other observations

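All tests in this part except the one on the second epithelial list were chosen after the results had been seen. Genes in the next 2 paragraphs were chosen after their values were seen.

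Single genes with lower values in the null testes, none past the threshold over all probes, included the following, which were not tested as a group. Tfap2c, a transcription factor of germ cell specification, was at -1.24 (SE 0.18, adjusted p = 0.0556, limma), Dppa5a at -1.52 (SE 0.26) and -1.17 (SE 0.20) on 2 probes, and Igf2bp1, an oncofetal RNA-binding protein, at -1.12 to -1.44 on 4 probes. Lin28a, which blocks maturation of let-7 microRNAs, was at -1.58 (SE 0.27) and -1.16 (SE 0.23) on 2 probes; it is a member of the undifferentiated list. In each of these but Igf2bp1, at which 2 of the 4 probes overlapped, the 3 null arrays lay below the 3 wild-type arrays.

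Single genes with higher values, also without passing and not tested as a group, were Wfdc15b at 3.41 (SE 0.73) and 2.51 (SE 0.64), Krt14, a basal keratin, at 2.46 (SE 0.62), Serpina3n, a protease inhibitor, at 2.04 (SE 0.34, adjusted p = 0.0922, limma), and Igfbp2, a binding protein of insulin-like growth factors, at 1.82 (SE 0.31). Gata3, a transcription factor of the mesonephric duct, was undetected on all wild-type arrays and at least 3.15-fold higher. Nudt6 lies on the chromosome of Foxo1: among the 200 tested genes nearest to Foxo1 it was the only called one, against 21 of 10931 others (Fisher's exact test, two-sided, p = 0.329). Among the nearest 100 it was also the only one, against 21 of 11031 others (Fisher's exact test, two-sided, p = 0.18). The test asks about the neighbourhood as a whole, so it cannot decide whether Nudt6 changed because of its place near Foxo1.

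The opposite changes of the 2 Foxo1 probes were weighed against technical explanations. The background correction or normalization is argued against by the deposited signals before either step: the lowest null signal of the higher probe was 3.42 times the highest wild-type one, and the highest null signal of the lower probe 0.683 times the lowest wild-type one. At either probe 0 arrays were out of place. Both probes were looked at because they were called with groups that do not overlap, so this cannot speak to an exchanged or mislabelled array. An altered Foxo1 transcript from the null allele, which keeps or gains the target of one probe and loses that of the other, may be the source; it is a hypothesis that stays untested without the probes' places in the gene, and cross-hybridization of the higher probe stays open too.

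The germ cell lists fell while the list of differentiating spermatogonia did not, by camera with the preset correlation; with an estimated correlation the adjusted p was 0.279 for the pan germ cell and piRNA lists (0.154 by fry) and 0.152 for the undifferentiated and GDNF lists. Dilution by RNA of another tissue would lower the Sertoli cell list alike, and the pan germ cell score changed by -0.95. The Sertoli score changed by -0.012 (SD 0.08 on the null arrays), so dilution is unlikely as the whole cause. It also stayed above -0.47, a limit set as a part of the pan germ cell change after the results were seen. A loss of germ cells of every kind alike would leave the difference between the differentiating and pan germ cell scores the same. This was 1.04 higher in null, at 0.79, 1.26 and 1.09 against -0.02 to 0.02 in wild type (exact permutation p = 0.1, the smallest possible). The 2 lists were set against each other because 1 had fallen and the other had not, so the difference restates the pattern. Only 5 of the 12 differentiating members are held to be germ cell restricted. For these the difference was 1.16, but their own values went both ways, and their scores ran from -0.46 to 0.69 in wild type. A loss of all germ cells alike thus stays undecided. A smaller share of undifferentiated cells among the germ cells, or lower transcription of these genes in cells that lack Foxo1, may account for the pattern as hypotheses; RNA of whole testes cannot separate them, and neither was tested.

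The epididymis and rete epithelium list was higher in the null arrays by camera with the preset correlation, but not past the threshold with an estimated correlation (adjusted p = 0.279) or by fry (adjusted p = 0.179). A lower share of germ cells that raises every other cell type alike would raise the Sertoli cell list as much. The Sertoli score changed by -0.012, and this list rose by 1.10 more, with all null arrays above the wild-type ones. The 2 lists were set against each other after 1 had been seen to rise and the other had not. The difference thus restates the pattern and leaves this explanation undecided. Epithelial tissue carried along in some dissections cannot be told apart from a change in the testis: a second epithelial list of 11 tested genes changed by 0.10, with 0.38 and 0.13 on null replicates 2 and 3, -0.21 on null replicate 1 and -0.11 to 0.20 in wild type, because its members went both ways. The brightest tested members of the first list were Wfdc2 (9.41 in wild type, 10.3 in null) and Krt8 (9.04 and 9.73), which other testis cells may express too; 6 of the 9 tested members were detected on all wild-type arrays. Lcn8, an epididymis-specific lipocalin, was at -0.15 (SE 0.16).

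The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 26 lower and 2 higher probes; for each count it was the only 1 of the 10 with as many, and the highest other was 0. It gave 10 lists past the threshold, and 2 of the 10 splits gave as many: the highest other, 11 lists, set wild-type replicates 1 and 2 with null replicate 1 against the rest. On the first principal component (34.6% of the variance) null replicate 1 lay at -3.93, between wild type (-24.0 to -16.5) and the other null arrays (27.1 and 37.0).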
